A study of Homo sapiens with 4 samples.

How the data were processed

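CTCF ChIP-seq was carried out on 4 samples of K562 cells, which the labels give as replicates 1 to 4 of 1 experiment. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was sheared to fragments of 200 to 500 bp, and the fraction bound by polyclonal antibodies was made into libraries for short-read sequencing. Nothing in the labels says whether the samples came from separate cultures.

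The authors deposited 1 list for the whole series. Per the file itself, each line gives a chromosome and the start and end of an interval in bp. All 45696 intervals are 1 bp wide and distinct, and the list carries no header, strand, sample, score, height or p-value. Per the design text in the labels, tag density was taken in 150 bp windows at 20 bp steps, enriched zones were found with the HotSpot algorithm at a false discovery rate of 1.0% set on random uniquely mapping 36-base reads, and peaks were then located inside these zones. The aligner, the software versions and the way the 4 samples were combined are not given in the sources used here. Because the list names no sample, the agreement of the replicates, the depth per sample and the precision of a site's position are unknown, and no interval that needs a read count is given. A site is an authors' call at their threshold, so weaker sites below it are not listed, and the list holds no 2 sites less than 201 bp apart.

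The submitters' processing notes name hg19 as the genome build. However, 166 positions lie past the ends of their chromosomes in hg19, with 124 on chromosome 19, 40 on chromosome 3 and 2 on chromosome 4, whereas none lies past a chromosome end in hg18 (NCBI36). Of the 19 hg18 centromeres that lie between the first and last site of their chromosome, 18 fell in the longest or second longest site-free interval of that chromosome. Centromeres of hg19 were not checked in this way, so these positions do not tell the builds apart. Because of the positions past the chromosome ends, coordinates are given as in the list, as end positions counted from 1, and read as hg18. Chromosome lengths, approximate centromere positions and the boundaries of the ends shared by X and Y in hg18 were taken from general knowledge of that public assembly, not from the series. No genome sequence or annotation of hg18 was used here, and the gene table at hand belongs to GRCh38.p14. No coordinate was converted or compared between builds, so no site was assigned to a gene from an annotation. A few loci named under the other observations were placed from general knowledge of hg18. From that table only the number of genes per chromosome was taken (20037 protein-coding genes over 24 chromosomes).

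Densities are sites per Mb of chromosome length unless stated otherwise. Relations across the 23 chromosomes other than Y were tested with Pearson's and Spearman's coefficients and 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 4 relations. Density in the outer 5 Mb of a chromosome was compared with the rest by 100000 sign flips over chromosomes, leaving out the short-arm ends of chromosomes 13, 14, 15, 21 and 22, for which the rest was taken per Mb from the first site onward, since no site was listed before it. Spacings were compared with 1000 random placements of each chromosome's own number of sites, by the Kolmogorov-Smirnov distance to the mean of 100 further placements. For single shares the two-sided p from placements is at least 0.002. Groups of sites were runs in which 6 or more lay within 10 kb of a first site. On simulated data, 0 of 20 uniform placements of 45696 sites reached a p of 0.05 in the spacing test, run with fewer placements than above. All 50 planted groups of 6 sites were recovered, but they lay within 10 kb by design, so this checks the code only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

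Before the data were examined, 8 results were planned: the map and the spacing, which are reported, and 6 that need replicate columns, scores, an annotation or a genome of the right build (agreement of replicates, sites at transcription start sites, sites near genes of fixed lists, the CTCF motif, motif orientation and peak strength), which were not computed. Of 17 gene lists fixed then, the 3 defined by a name pattern were used, as numbers per chromosome; the others need positions and were not analysed here. The rule for items named in the text was also fixed then: the 5 richest 1 Mb bins (6 with ties), the 5 longest site-free intervals outside centromeres, and genes of the lists, which could not be placed. The gene density relation, the chromosome ends and the groups were added after the list had been seen, as were their alternatives. For the richest bins and the site-free intervals only the choice of items to name was fixed before: their comparison with random placements and the alternatives for the richest bin were also added after. Alternatives were merging sites less than 500 bp apart, autosomes only, other placements, other windows and shifted bins.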

Results

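The data are a single map of binding sites of CTCF, the zinc-finger DNA-binding protein that marks chromatin boundaries in vertebrates and acts at many insulators, in K562 cells. K562 is an established human erythroleukemia cell line that is widely used as a model of the erythroid lineage. Sites were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA crosslinked to the protein is recovered with an antibody and sequenced. The series holds 4 samples, which the labels number as replicates 1 to 4 of 1 group, with no control, treated or other-cell group. The title places the map in a search for insulator elements that could be used in gene therapy, so the question the data address is where CTCF sites lie in this genome and how they are arranged. The deposited list gives 45696 sites, each as a single base position, in 1 list for the whole series. Positions fit the hg18 assembly and are given in it, although the submitters' processing notes name hg19. It marks neither the replicate in which a site was found nor its strength, so there is no replicate error on the values below and the depth behind each site is unknown. Errors are therefore spreads over chromosomes or over random placements of the same number of sites.

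The list held called CTCF sites on every chromosome. The 22 autosomes held 44341 sites, the X chromosome held 1354 and the Y chromosome held 1. The single call on Y is not interpreted as a site, because the list gives no depth or score to judge it by. The mean density over the 23 chromosomes other than Y was 16.01 ± 5.997 sites per Mb (SD over chromosomes, n = 23). Chromosome 19 was the densest, with 2070 sites or 32.4 per Mb, followed by chromosome 17 with 2235 sites or 28.4 per Mb. Chromosome 13 was the sparsest autosome, with 751 sites or 6.58 per Mb, so the density of chromosome 19 was 4.93 times that of chromosome 13. The X chromosome had 8.74 sites per Mb, below every autosome except chromosome 13. Chromosome 13 has a short arm without sites, and when densities were taken over the span from first to last site the ratio to chromosome 19 was 4.16. Chromosome 22, which also has a short arm without sites, had 21.3 sites per Mb of its length and 30.2 per Mb of its span. The number of copies of each chromosome in these cells was not measured, so its part in these densities is unknown.

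Density followed gene content. Chromosomes with more protein-coding genes per Mb had more CTCF sites per Mb, from chromosome 13 with 2.96 genes and 6.58 sites per Mb to chromosome 19 with 22.7 genes and 32.4 sites per Mb. Across the 23 chromosomes Pearson's r was 0.93 and Spearman's rho was 0.88, and both had a permutation p of 1e-05, the smallest the permutations can give (Benjamini-Hochberg adjusted 4e-05 over 4 relations). Without chromosomes 17 and 19, the farthest from the median gene density, r was 0.91 (permutation p = 1e-05). The number of sites per protein-coding gene had a median of 2.44 with an SD of 0.395 over chromosomes. It was lowest on chromosome 19, at 1.43, and on the X chromosome, at 1.60, and highest on chromosome 18, at 3.18. Chromosomes are not replicates, and the gene numbers come from a later assembly than the sites. No input DNA was used, so differences in copy number between chromosomes were not separated from gene content.

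**Figure D1:**
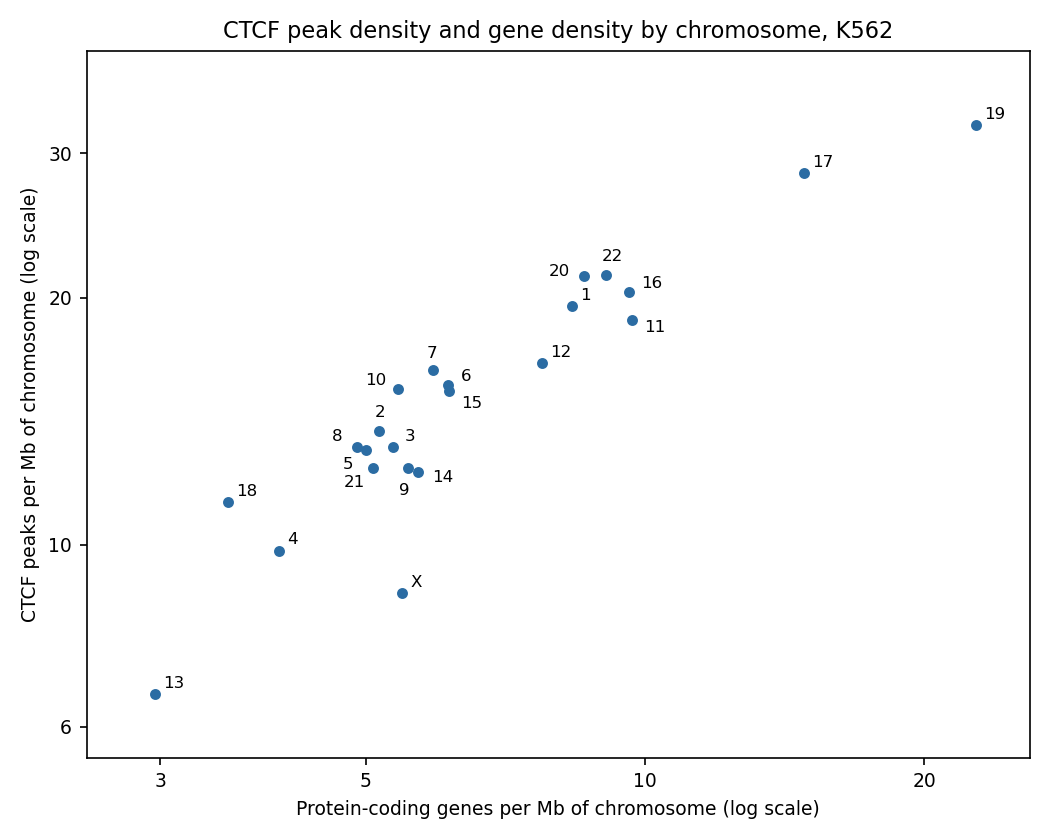
CTCF sites per Mb (vertical, log scale) against protein-coding genes per Mb (horizontal, log scale), with 1 point for each of the 23 chromosomes other than Y, labelled by name. Density rises with gene content from chromosome 13 (6.58 sites per Mb) to chromosome 19 (32.4 sites per Mb), and the X chromosome (8.74 sites per Mb) lies below chromosomes of similar gene content.

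The same comparison was made for 3 gene families whose name patterns were fixed before the data were examined. Zinc-finger genes named ZNF, many of which encode repressors of transposable elements, numbered 477 and lay largely on chromosome 19, with 240 members. Their density went with that of CTCF sites over all 23 chromosomes (r = 0.63, adjusted permutation p = 0.00388; rho = 0.50, adjusted permutation p = 0.0219). The relation rested on chromosomes 16 and 19, since r was 0.37 without them (permutation p = 0.0973). For the 390 olfactory receptor genes r was 0.29 (adjusted permutation p = 0.200) and rho was 0.51 (adjusted permutation p = 0.0219), and without chromosomes 11 and 19 neither passed 0.05 (r = 0.33, permutation p = 0.149; rho = 0.42, permutation p = 0.0564). For the 70 replication-dependent histone genes r was 0.00 (adjusted permutation p = 0.997) and rho was 0.11 (adjusted permutation p = 0.630), but 68 of them lay on chromosomes 1 and 6 and 19 chromosomes had none, so chromosome totals could hardly show a relation for this family.

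Sites were denser toward the chromosome ends. The outer 5 Mb held 25.5 ± 9.71 sites per Mb and the rest of the chromosomes 16.04 ± 6.52 (SD over chromosomes, n = 23), a mean difference of 9.50 ± 9.70 (SD, permutation p = 0.0001 by sign flips over chromosomes, two-sided). For chromosomes 13, 14, 15, 21 and 22, which begin with a long stretch without sites, only the long-arm end was used and the rest was taken per Mb from the first site onward. The rest still included the site-free intervals that spanned centromeres, such as 10.1 Mb on chromosome 16 and 3.86 Mb on chromosome 21. These lower its density, and no alternative left them out. The chromosomes are not replicates here either. Genes were not placed along the chromosomes, so the difference was not separated from gene content. The ends were denser on 20 of the 23 chromosomes. The contrast was widest on chromosome 21, with 41.0 sites per Mb at its long-arm end against 11.7 elsewhere, on chromosome 14 with 40.6 against 13.3, and on chromosome 16 with 46.2 against 17.1. The 3 exceptions were chromosome 22, with 18.6 at its end against 32.0 elsewhere, chromosome 15, with 18.2 against 18.9, and chromosome 10, with 15.1 against 15.5. With the rest taken over the whole length of these chromosomes, chromosome 15 was no exception (15.2 sites per Mb in the rest), chromosome 22 had 21.6 in the rest, and the ends were denser on 21 of 23.

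At the scale of 1 Mb, sites were spread unevenly. Over 3033 bins of 1 Mb the median was 12 sites per bin, 251 bins held none, and the richest 10% of bins held 29.5% of all sites. The variance of the bin counts was 11.6 times their mean, against 2.61 on average when each chromosome's own sites were placed at random along it, and the highest of 1000 random placements gave 2.70. Bins and placements covered centromeres, short arms without sites and sequence missing from the assembly, which adds to the empty bins and the variance. Chromosomes 9 and 13 held the most empty bins, 35 and 26. No bin count was taken without such stretches. Of the 77 bins with 50 or more sites, 17 lay on chromosome 19, 11 on chromosome 1 and 10 on chromosome 17, while chromosomes 2, 4, 13, 15, 18, 21 and X had none. The richest bin held 92 sites, between 18 and 19 Mb on chromosome 22. It was followed by the bin from 64 to 65 Mb on chromosome 11 with 72 sites. A further 4 bins held 70 sites each, at 154 to 155 Mb on chromosome 1, 150 to 151 Mb on chromosome 7, 71 to 72 Mb on chromosome 17 and 18 to 19 Mb on chromosome 19. No random placement had a bin with more than 57 sites.

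Neighbouring sites lay closer together than random placement gives. The median spacing of adjacent sites was 25.3 kb, with quartiles of 8.56 and 65.2 kb, against a mean random median of 43.0 kb when sites were placed anywhere in their chromosome, 30.3 kb when the number of sites in each 1 Mb bin was kept and 26.8 kb when it was kept in each 100 kb bin. Observed and random spacings differed by a Kolmogorov-Smirnov distance of 0.162 (permutation p = 0.001, the smallest that 1000 placements can give), with the observed excess of short spacings greatest at 25.7 kb. Spacings under 1 kb made up 3.67% of the 45672 adjacent pairs, 2.22 times the share of 1.66% in placement anywhere in the chromosome, and spacings under 10 kb made up 28.0%, 1.83 times that random share. The differences were smaller when placements kept regional density: the distance was 0.0623 with the 1 Mb counts kept and 0.0333 with the 100 kb counts kept, both with a permutation p of 0.001. With the 100 kb counts kept, spacings under 1 kb were 1.24 times, those under 5 kb 1.23 times and those under 10 kb 1.13 times as frequent as at random (each two-sided permutation p = 0.002). Spacings under 50 kb were then 0.997 times as frequent (permutation p = 0.1). No pair lay less than 201 bp apart, while random placements had no such floor, so the comparison of shares under 500 bp, which was also run, is not interpreted. Peaks were located in tag density taken over 150 bp windows, and spacings near or below that resolution were not interpreted.

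**Figure D2:**
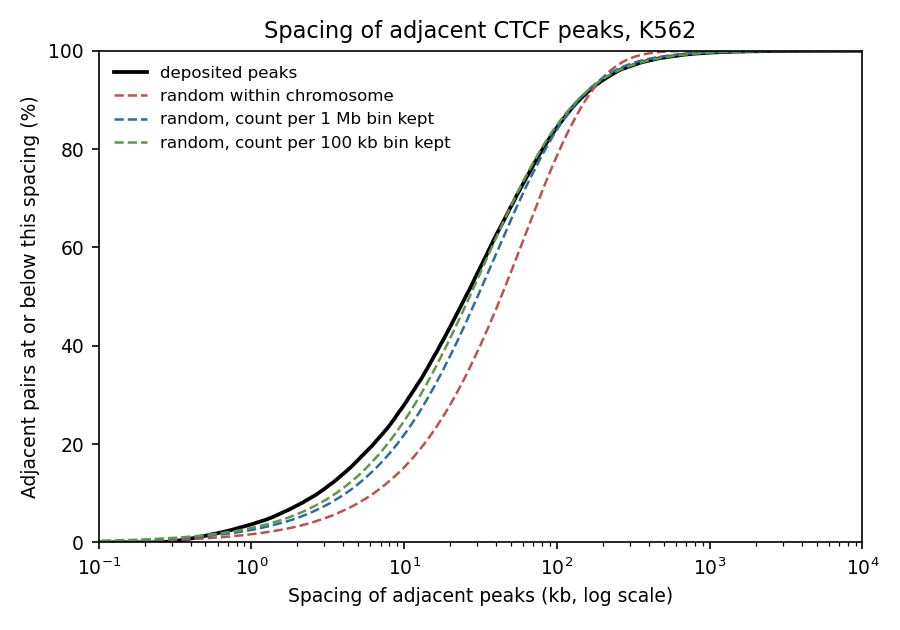
Cumulative share of adjacent CTCF site pairs (vertical, %) by spacing (horizontal, kb, log scale) for the deposited list (solid) and for the mean of 20 random placements of each kind (dashed). The deposited list lies left of all 3 random curves between about 1 and 20 kb, with a median of 25.3 kb against 43.0 kb for placement anywhere in the chromosome and 26.8 kb with the 100 kb counts kept.

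The tightest groups of sites were few. Runs in which 6 or more sites lay within 10 kb of a first site occurred 7 times in the genome. Random placement within chromosomes gave 0.092 such groups on average and never more than 2. Placement that kept the 1 Mb counts gave 1.76 on average, and 1 of 1000 placements gave as many as 7. With the 100 kb counts kept, the mean was 4.90 and 212 of 1000 placements gave 7 or more. These few groups thus did not stand out from the local density at 100 kb. That comparison can miss an excess, because a group adds to its own 100 kb count and random sites had no floor of 201 bp. The group with the most sites, 9, spanned 13.99 kb on chromosome 22 from position 18084912 to 18098897. The most compact set of 7 sites in the genome spanned 4.49 kb on chromosome 11, from 1976340 to 1980825, and the next most compact set of 7 took 8.25 kb. Groups of 7 lay on chromosome 1 from 153323370 to 153333706 and on chromosome 19 from 45792600 to 45803455. Groups of 6 lay on chromosome 2 from 232280131, on chromosome 12 from 119148484 and on chromosome 16 from 31370773. After sites less than 500 bp apart were merged, 3 groups met the same definition, and the set on chromosome 11 was not among them. Groups of 5 or more sites within 10 kb numbered 75, against a mean of 17.4 and at most 32 with the 1 Mb counts kept. They were not compared with placements that kept the 100 kb counts.

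Long stretches held no site at all. Stretches before the first or after the last site of a chromosome, such as the start of chromosome 21, were not counted. Adjacent sites lay more than 1 Mb apart in 174 places, 18 of which spanned a centromere. The widest of these spanned the centromere of chromosome 9 (22.03 Mb) and that of chromosome 1 (20.7 Mb). Of the 156 that spanned no centromere, chromosomes 2 and 4 held 19 each, the X chromosome 15 and chromosomes 3 and 13 held 13 each, while chromosomes 15, 19 and 22 held none. The longest was 6.69 Mb, on chromosome 9 between 19916156 and 26604094, 1.79 times the next. That one, of 3.73 Mb, followed on the same chromosome between 28063478 and 31790216. The other 3 of the longest 5 lay on chromosome 9 from 38717571 to 41963649 (3.25 Mb), on chromosome 18 from 59813194 to 62923112 (3.11 Mb) and on chromosome 9 from 81980193 to 84766462 (2.79 Mb). Random placement of each chromosome's sites never left an interval longer than 2.02 Mb, and 26 observed intervals outside centromeres were longer than 2 Mb. Sequence that is missing from the assembly or to which short reads do not map uniquely is also free of sites, and neither was separated here.

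**Figure D3:**
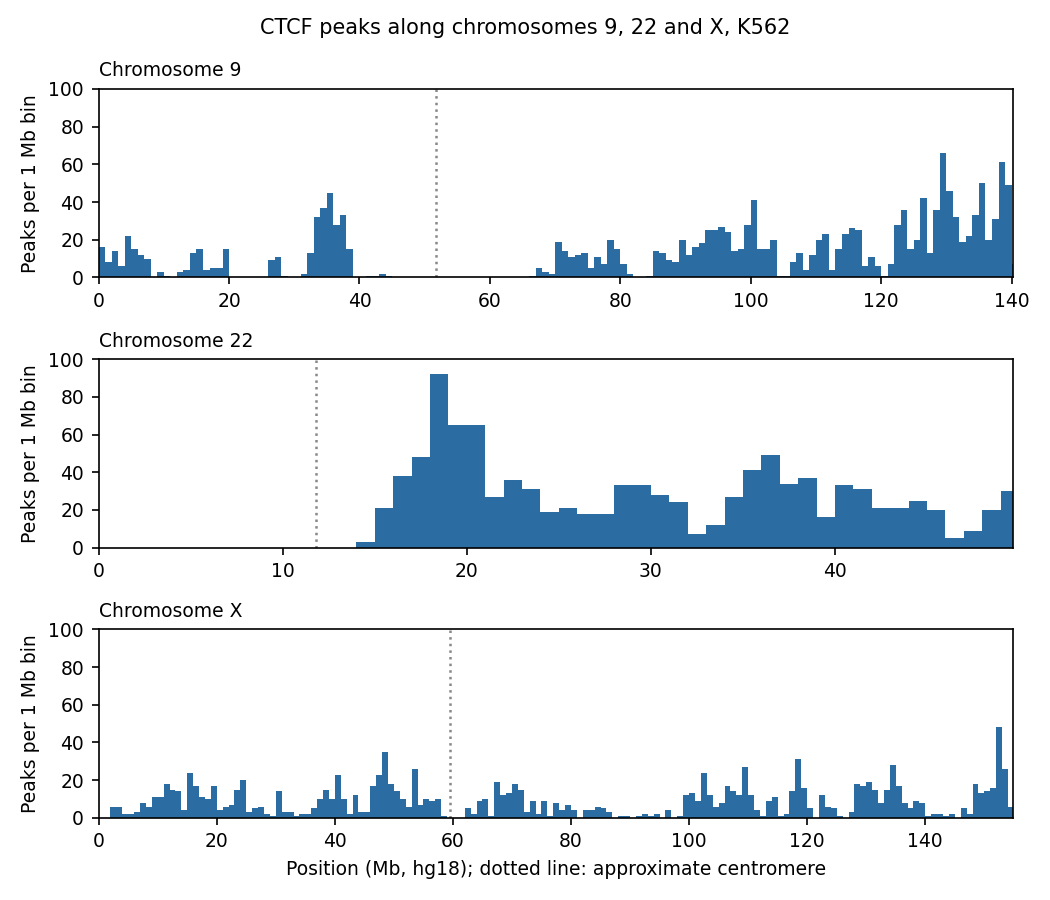
CTCF sites per 1 Mb bin (vertical) along chromosomes 9, 22 and X (horizontal, Mb in hg18). Dotted lines mark approximate centromeres. Chromosome 9 has no site between 19916156 and 26604094, and chromosome 22 reaches 92 sites in the bin from 18 to 19 Mb.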

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

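Of 24 alternative values for 7 results, 21 kept the direction, the side of the threshold or a value close to the main one. This tally is a weak check: merging or leaving out X and Y could hardly change the number of sites. For the spacing, p stayed at its smallest possible value although the distance fell. Planned before the data were examined were merging sites less than 500 bp apart, autosomes only and placement between the first and last site. The other alternatives were chosen after seeing the data. The number of sites was 45078 after merging and 44341 on autosomes. The spacing distance ranged from 0.0333 with the number per 100 kb bin kept to 0.162 on autosomes, each with a permutation p of 0.001. The correlation of site and gene density ranged from 0.86 over the span of sites to 0.96 with all annotated genes, and leaving out 1 chromosome at a time moved it between 0.92 and 0.94. The excess at chromosome ends was 11.99 sites per Mb in the outer 2 Mb and 6.40 in the outer 10 Mb, and 10.4 with the rest taken over the whole chromosome length. The number of groups of 6 sites within 10 kb, 7, was 3 after merging at 500 bp, since counting close sites once removes members. It was 75 with 5 sites within 10 kb, a looser definition. Random placement then gave 2.07 on average within chromosomes and 17.4 with the 1 Mb counts kept. The density ratio of chromosome 19 to chromosome 13 was 4.16 over the span of sites. The richest bin held 92 sites also with bins shifted by 0.5 Mb. Of the 23 settings listed before the data were examined, 18 were not run, because the list has no score or replicate column and no genome or annotation of its build was used, so no replicate could be left out. Depth is unknown and sets no limit that can be computed.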

Other observations

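The loci in this paragraph were chosen after their values were seen and are named from general knowledge of hg18, not from an annotation. The most compact set of 7 sites in the genome, on chromosome 11 from 1976340 to 1980825, lies at the imprinting control region between IGF2, a fetal growth factor gene, and H19, a noncoding RNA gene. This region is a textbook insulator bound by CTCF on the maternal allele. Its 7 sites were spaced 532, 910, 840, 1422, 392 and 389 bp apart, and the next site followed after 34.0 kb. Farther along the same chromosome, the sites at 5182778 and 5269245 flanked an interval of 86.5 kb without any site, in which the beta-like globin genes lie. The flanking sites fall where the boundary elements of that locus are known, beyond the 3' end of the globin cluster and at the far end of its locus control region. An interval of that length was not unusual, since 18.5% of all spacings and 14.4% of those on chromosome 11 were longer.

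In the paragraphs that follow, the tests of chance spacing and of merged groups were specified before their results were seen. The tests of DNA loss, of shared X and Y sequence, of groups of 6 and of copy number were chosen afterwards.

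The longest interval between adjacent sites that spanned no centromere was 6.69 Mb, on chromosome 9 between 19916156 and 26604094. It was longer than any interval in 1000 random placements (0 of 1000 as long). This argues against chance spacing at the density of the chromosome, although that model also fails to give other long intervals. A hypothesis is that the DNA is absent: K562 is known to lack both copies of the CDKN2A region, which lies inside this interval. A loss would cut through sequence of ordinary density, and the 1 Mb on either side held 32 sites together (15 and 17), more than at 37 of the 39 next longest intervals, whose median was 14. This is consistent with an abrupt loss. A stretch that is naturally poor in sites but has sharp edges, or one to which reads do not map uniquely, stays open, since no sequencing of input DNA was used here.

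The X chromosome had no site before position 2740660. None of 1000 random placements left its start free that far (0 of 1000), the mean density of X would put 23.95 sites there, and the same length at the start of 17 other chromosomes held 9 to 153 sites (median 70). A candidate explanation is that reads from sequence shared by X and Y were discarded as not uniquely mapped: with boundaries written from general knowledge of hg18, the first site lay 31.1 kb beyond the boundary of the shared end and the last site of X 38.9 kb before the other boundary, both less than the median spacing on X of 44.1 kb. No site on X or Y fell in the shared ends, which says little for Y, since it held only 1 site in all. A loss of the tip of X in these cells would also remove the sites and was not tested, and no biological explanation was tested.

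The richest 1 Mb bin, with 92 sites at 18 to 19 Mb on chromosome 22, was not matched by any of 1000 random placements (0 of 1000), which argues against chance spacing at the density of the chromosome. That model also fails to give other rich bins, since its highest bin held 57 sites against 72 in the second richest observed bin. When sites less than 10 kb apart were merged, the chromosome 22 bin fell to rank 146 with 25 merged sites. With the sites of each bin placed at random inside it, 39 remained and it stayed at rank 1, but only 1 such placement was made, so the spread is unknown. The lead of the bin was thus lost when close neighbours were merged. It did not rest on the tightest groups alone, because 83 sites were left without groups of 6 or more within 10 kb, against 72 in the second richest bin. The 3 bins from 18 to 21 Mb averaged 74 sites, against 31.3 in the next 3 bins and 35.7 in the 3 before, and the richest other bin of the chromosome held 49. K562 is known to carry extra copies of a part of chromosome 22 next to BCR, and extra copies could raise the number of called sites. The bounds of that part were not placed here, so the contrast between these bins does not mark it. An effect of extra copies cannot be told apart from local gene content, since neither input DNA nor an annotation of this build was used.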
